A study of Mus musculus with 8 samples.

How the data were processed

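Gene expression in LSK and GMP cells of wild-type and ACKR1-deficient mice was measured on 1-colour Agilent arrays. Per the labels, the deficient line had been backcrossed onto C57Bl/6J, the controls were wild-type littermates, the mice were 12 weeks old and female, RNA was extracted with Trizol, and cRNA was labelled with Cy3 using a low-input amplification kit. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, which the submitters' processing notes also name, and the design was annotated on genome build mm9. Per the file headers, the processed signal of each spot is a fluorescence intensity on a linear scale, corrected for background by Feature Extraction, and the median foreground and background signals are uncorrected intensities. The table of normalized values deposited by the authors holds log2 values. Set against the scanner values, its columns corresponded to log2 processed signal shifted to the 75th percentile and centred on each probe's median over the arrays (r between 0.999691 and 0.999965), which leaves none of scale, centring or direction unknown at that precision. Its column medians were 0.12 and −0.27 in wild-type LSK, 0.041 and 1.25 in deficient LSK, −0.13 and −0.14 in wild-type GMP, and 0.32 and −0.11 in deficient GMP. Other steps the authors took are not given in the sources used here.

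The arrays lay on 1 slide read in 1 scan. Deficient samples were in slide column 1 and wild-type samples in column 2, so column and genotype cannot be told apart. Wild-type and deficient arrays of a population with the same replicate number lay in 1 slide row (LSK in rows 1 and 3, GMP in rows 2 and 4). Each array had 62976 spots, of which 59305 were not controls. No spot was saturated (0 on each array) and 104 to 139 spots per array were flagged by Feature Extraction as outliers. Signal over background sets the depth of an array: deficient LSK replicate 2 had 34.3% of spots well above background and the others 62.5% to 73.1%. These 2 arrays, deficient LSK replicate 2 for its weak signal and deficient GMP replicate 1 for its distance from the other GMP arrays, were left out together as an alternative chosen after seeing the data.

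The log2 processed signal was taken minus the 75th percentile of the array. Control spots and outlier spots were left out and spots of 1 probe were averaged. Probes were kept if well above background on both arrays of at least 1 group (39098 of 55681). The files carry no gene name column, so the accession of each probe was looked up in an NCBI RefSeq gene table of the GRCm38.p6 assembly, which was used for names and for the order of neighbouring genes alone. A symbol was found for 26582 probes (20145 symbols). Each gene was represented by the probe with the highest mean over the arrays, and 28088 features were tested, 15856 of them with a symbol. Several kept probes existed for 3913 symbols. Among called genes with several probes, a probe of opposite sign occurred for 0 of 4 in LSK, 0 of 5 in GMP, 1 of 14 in the average (Mgll) and 2 of 71 between populations in wild type (Col16a1 and Hif3a).

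Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes on 4 group means over the 8 arrays, with 4 residual and 5.74 prior degrees of freedom). A feature was called at a Benjamini-Hochberg adjusted p under 0.05. Counts at an unadjusted p under 0.05 are given for scale, as with no difference a share of 0.05 of the features would pass. The contrasts were deficient minus wild type in LSK, in GMP and averaged over both, the difference between the former pair, and GMP minus LSK in each genotype. Where a probe was not well above background on either array of the dimmer group, the fold is a lower bound, written "at least": the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background on that array. It is no strict bound where an array of the brighter group was not well above background either. In the averaged comparison, each population's difference was set to its bound where it had one and the mean of both was taken, a step chosen after seeing the data. Files were read with the data.table package, version 1.17.8, and figures drawn with Python 3.11.15 and matplotlib 3.10.9. The fit was tested on simulated data with 50 genes changed at each of 4 sizes per comparison.

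Before the data were examined, 30 gene lists, the tests, the contrasts, most alternatives and the rule for named genes were fixed. The lists cover stem cell identity, lymphoid priming, the granulocyte-monocyte programme, primary granules, secondary and tertiary granules, neutrophil surface receptors, monocytes and macrophages, dendritic cells and MHC class II, erythroid cells, haem biosynthesis, megakaryocytes and platelets, B lineage, T and NK cells, mast cells with basophils and eosinophils, stroma and endothelium, mitosis, DNA replication, cell-cycle inhibitors and p53 targets, interferon response, inflammatory response, chemokine receptors, chemokines, immediate early genes, heat shock and unfolded protein, ribosomal proteins, oxidative phosphorylation (the respiratory chain), glycolysis, cholesterol synthesis, the chromosome 1 neighbours of Ackr1, and female and male genes. The last had fewer than 5 tested members and is given as values. The other 29 were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation as an alternative, and with fry beside it, which tests whether the members move on balance 1 way and compares no list with other genes. With camera 18, 12, 14, 16, 21 and 12 lists were called in LSK, GMP, the difference between them, the average, and GMP against LSK in wild-type and deficient mice. With an estimated correlation the numbers were 1, 3, 0, 3, 1 and 0, and with fry 6, 3, 0, 5, 11 and 4. A list median quoted "with members at their bound" sets each member that has only a bound to that bound, or to 0 where both groups are dim or no bound keeps the direction, and is given where it differed by more than 0.1.

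The text names, in LSK, GMP and wild-type populations, the 10 genes with the largest difference on each side among those called whose groups do not overlap, and 5 a side for the other contrasts. Where fewer passed, all that passed were named, then genes by the smallest unadjusted p until there were 5 a side, as values. Predicted gene models were counted and not named. From each list up to 4 called members with the largest difference and up to 2 uncalled members with the highest mean signal were eligible, and 16 genes of the gates and lineages were fixed by name. Some genes that this rule takes are not reported here, though they count in their lists and among the named called genes.

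The alternatives were normexp correction (offset 50) of the median signals, quantile normalization, scaling to the median of kept probes, no filter, a filter on all arrays, the mean of a gene's probes, a trended and robust prior variance, the authors' normalized values, a fit of the compared groups alone, the replicate number as a block within each population, and leaving out each array in turn, which assumes that the lone array of a group varies like the other groups. Mean foreground signals were not used here, so normexp took the median signal with the median background. Alternatives chosen after seeing the data were array weights, the 2 arrays left out together, replicate numbers crossed in LSK, and the overlap of genotype calls with each population fitted alone.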

Results

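Gene expression was measured in progenitors sorted from the bone marrow of wild-type mice and of mice lacking ACKR1, an atypical receptor that binds chemokines without G protein signalling. The LSK population (lineage-negative, Sca1-positive, cKit-positive) holds haematopoietic stem cells and multipotent progenitors. The GMP population (lineage-negative, Sca1-negative, cKit-positive, positive for CD34 and CD16/32) holds granulocyte-monocyte progenitors. There were 8 arrays in 4 groups, with 2 arrays for each population and genotype. All levels are log2 signal over the 75th percentile of the same array, and every difference between genotypes is deficient minus wild type (n = 2 arrays per group, SD given beside group means). The labels do not say whether each array held RNA of a separate animal, so p-values measure only the spread between these samples, which may be technical.

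Signal differed between arrays. On 7 arrays, between 62.5% and 73.1% of spots were well above background, whereas deficient LSK replicate 2 had 34.3%, and its 75th percentile of signal was 24.6 against 197 to 770 on the others. Across features, that array correlated with the others at r between 0.690 and 0.784. Deficient GMP replicate 1 also stood apart, with r of 0.898 to its own replicate and 0.905 to deficient LSK replicate 1, against 0.976 between the wild-type GMP arrays, and Fcgr3, which encodes CD16, had a mean of 0.72 with an SD of 2.09 in deficient GMP. The number of arrays limits the precision of every value. In simulated data of the same size, 60% of genes changed by a log2 of 4 were recovered in LSK, 52% in GMP and 96% in the averaged genotype comparison, while a log2 change of 1 was recovered for 0%, 0% and 2% of genes. The simulation gave each gene the same spread in all groups, whereas array weights were 0.317 in deficient LSK and 3.98 in wild-type GMP. Recovery in the real data may therefore differ.

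The transcript of the disrupted gene, Ackr1, was not called between genotypes at its probe, in a design that recovers few changes of a log2 of 1. Its level was −0.85 (SD 0.28) in wild-type and −0.77 (SD 0.11) in deficient LSK, and −0.47 (SD 0.039) in wild-type and −0.12 (SD 0.065) in deficient GMP. The differences were 0.08 in LSK (limma, adjusted p = 0.954) and 0.36 in GMP (adjusted p = 1), where both deficient arrays lay above both wild-type ones. The probe was well above background on 7 of the 8 arrays, the exception being deficient LSK replicate 2. The labels do not say whether the probe lies in the deleted part of the gene, so its level checks nothing about the genotype labels.

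The first comparison asked how expression differed between deficient and wild-type LSK, which also lay in different slide columns. Members of the secondary and tertiary granule list were among the genes that rose the most. Mmp8, the neutrophil collagenase, rose at its probe by a log2 of 11.08 (SE 0.816, limma, adjusted p = 0.00167), at least 876-fold because it was not well above background on either wild-type array. Retnlg, a resistin-like protein of granulocytes, rose by 10.61 (SE 0.756, adjusted p = 0.00167), from −5.36 (SD 0.13) to 5.25 (SD 0.10). Ngp, a neutrophil granule protein, rose by 9.97, Camp, the cathelicidin precursor, by 8.72 and Ltf, which encodes lactoferrin, by 8.30, with adjusted p between 0.00605 and 0.0114. S100a9 and S100a8, the calprotectin subunits, rose by 8.91 and 8.24, and Itgb2l rose at least 239-fold. Alas2, the erythroid enzyme of haem synthesis, rose by 8.20 and Rhd, the Rhesus antigen of red cells, by 7.69 (adjusted p = 0.0484). Of the named called genes of LSK, Retnlg, Ngp, Alas2, Rhd, Ms4a1 and Itln1 were well above background on 1 of the 2 wild-type arrays.

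In all, 67 of 28088 features were higher in deficient LSK and 0 were lower, and 52 of the 67 carried a gene symbol. The all-feature median difference was 0.115, and −0.081 without deficient LSK replicate 2, the array with the weak signal. At an unadjusted p under 0.05, limma gave 2475 features. The named genes with the smallest p on the lower side did not pass: Dusp23, a phosphatase gene, had −2.94 (adjusted p = 0.299), Cradd −2.41, Tmem258 −2.88, Rps28 −2.15 and Ost4 −3.88 (adjusted p between 0.427 and 0.439). Without deficient LSK replicate 2, 0 features passed (1104 at an unadjusted p under 0.05) and so did 0 of the 20 named called genes, without wild-type replicate 1 or 2 the count was 2 or 4, and without deficient LSK replicate 1, which leaves the weak array alone in its group, it was 2818, of which 1131 were lower. With deficient LSK replicate 2 and deficient GMP replicate 1 both left out, 37 features passed, 21 of them among the 67, and quantile normalization gave 27.

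Among the gene lists, the members of the secondary and tertiary granule list rose together in deficient LSK, with 19 of 20 members above 0, 11 called over all features and 17 higher and 1 lower adjusted over the list alone. Their median difference was 6.95 (camera, adjusted p = 2.97e-31, and adjusted p = 0.0136 with an estimated correlation). Lcn2, which encodes lipocalin 2, had 4.47 and Ltb4r1 1.54, and neither passed (adjusted p = 0.062 and 0.551). The erythroid list rose by a median of 2.26 (adjusted p = 1.29e-15, but adjusted p = 0.101 with an estimated correlation), with 5 of 27 members called and 17 adjusted over the list alone. Slc4a1, the red-cell anion exchanger, rose by 5.94 (adjusted p = 0.0106), whereas Hba-a2, an alpha globin gene, had 8.64 and did not pass (adjusted p = 0.0618). The B lineage list rose by a median of 1.06 (adjusted p = 0.00012, and adjusted p = 0.101 with an estimated correlation). Its called member was Ms4a1, which encodes CD20, with 5.97 (adjusted p = 0.0303), and 4 of its 15 members passed adjusted over the list alone. Cd79b, a subunit of the B cell receptor, had −0.82 and did not pass. These 3 lists kept their call and direction without either array that stood apart, with medians of 7.53, 2.72 and 0.88 when both were left out.

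Other lists of mature myeloid cells moved less. Neutrophil surface receptors had a median of 0.41 (adjusted p = 0.000465), with 3 of 27 members called and 7 adjusted over the list alone. C5ar1, the C5a receptor, rose at least 35.2-fold, and Cxcr2, the receptor for neutrophil-attracting chemokines, by 4.46, from −3.54 (SD 0.16) to 0.92 (SD 0.54). Fpr2, a formyl peptide receptor, rose by 6.69. That value is not exact, as 0 wild-type arrays and 1 deficient array were well above background at its probe. The granulocyte-monocyte programme had 0.40 (adjusted p = 0.0181), with Cebpe, a factor of terminal granulocyte differentiation, higher by 4.94 and Fcnb at least 26.3-fold, and 3 of its 20 members passed adjusted over the list alone. Chemokine receptors had 0.44 (adjusted p = 0.0439, 2 of 16 adjusted over the list alone), monocyte and macrophage genes 0.95 (adjusted p = 0.00143, 5 of 20) and mast cell, basophil and eosinophil genes 0.98 (adjusted p = 0.000543, 6 of 23). Without deficient LSK replicate 2 the mast cell list had a median of −0.028, with a test still pointing up. With an estimated correlation none of these 5 passed, with adjusted p = 0.182, 0.409, 0.509, 0.38 and 0.103 in the order given. Without deficient LSK replicate 1 the receptor, programme, monocyte and chemokine receptor lists were no longer called, with adjusted p of 0.336, 0.973, 0.428 and 0.193 and a programme median turned to −0.048, and without wild-type LSK replicate 1 the programme, monocyte and chemokine receptor lists were not called either (adjusted p = 0.336, 0.211 and 0.176). Normexp correction ended the same 4 calls (adjusted p between 0.0589 and 0.364), and chemokine receptors also lost theirs without deficient LSK replicate 2 (0.125, adjusted p = 0.052).

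Housekeeping and stem-cell lists lay lower in deficient LSK, with 0 members called over all features and 0 adjusted over the list alone by limma. Ribosomal proteins had a median of −1.15 with 33 of 34 members below 0 (adjusted p = 2.08e-09, and adjusted p = 0.127 with an estimated correlation), and the respiratory chain list had −1.21 with 33 of 33 below 0 (adjusted p = 3.1e-10, and 0.35 as the adjusted p with an estimated correlation). Both kept the call without each array in turn, and the all-feature median shifted from 0.115 to −0.248 under quantile normalization without ending it. Heat shock genes had −1.13, glycolysis −1.0, the inflammatory response −0.98, the interferon response −0.93, immediate early genes −0.83, DNA replication −0.78, genes of haematopoietic stem cell identity −0.72 and cell-cycle inhibitors with p53 targets −0.52. Their adjusted p lay between 0.000181 and 0.0404, and between 0.38 and 0.593 as the adjusted p with an estimated correlation. Without deficient LSK replicate 2 all 8 lost the call, with stem cell identity at −0.27, the interferon response at −0.24 and DNA replication turned to 0.15, and the test for DNA replication also turned under quantile normalization. DNA replication, cell-cycle inhibitors, the inflammatory response and glycolysis also lost it without wild-type LSK replicate 2 (medians −0.54, −0.58, −0.45 and −0.73). With the replicate number as a block, DNA replication and the chemokine receptors lost the call in LSK (camera, adjusted p = 0.0528 and 0.0553).

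The remaining lists were not called in LSK. Lymphoid priming had a median of −0.81 (adjusted p = 0.0607), T and NK genes 0.58 (adjusted p = 0.0685), mitosis −0.41 (adjusted p = 0.0916) and cholesterol synthesis −0.46 (adjusted p = 0.107). Mitosis was called lower without deficient LSK replicate 1 (−1.47, adjusted p = 0.00142), without wild-type LSK replicate 1, under normexp correction and with no filter, but higher without deficient LSK replicate 2 (0.43, adjusted p = 0.0277). Lymphoid priming was called lower in 5 of 21 settings, and its median was 0.144 without deficient LSK replicate 2. Haem biosynthesis had 0.14, dendritic cell and MHC class II genes −0.21, chemokines 0.42 and megakaryocyte and platelet genes 0.12 (adjusted p between 0.252 and 0.866), with the sign of the first turned under normexp correction, quantile normalization and median scaling (−0.075, −0.067 and −0.113), the second under normexp (0.20), and the last pair under quantile normalization (−0.38 and −0.37). Haem biosynthesis was called under quantile normalization (adjusted p = 0.0317, with a test pointing up), without wild-type LSK replicate 2 (0.53, adjusted p = 0.0349) and without deficient LSK replicate 2 (0.96, adjusted p = 6.17e-05). The primary granule list had a median of −0.47 but a mean of 0.16 (adjusted p = 0.863). The called member of this list, as fixed beforehand, was Hp, the haptoglobin gene, with 6.12 (limma, adjusted p = 0.0122). Stroma and endothelium had a median of 0.34 with a test pointing down (adjusted p = 0.866). The chromosome 1 neighbours of Ackr1 had a median of −0.093 and a mean of 0.30 (adjusted p = 0.687), and 1 of 74 was called, Itln1, an intelectin gene, with 5.71. Markers of the sorted cells did not pass, with Kit at −1.76, Ly6a, which encodes Sca1, at −3.16, Cd34 at −0.94, Flt3 at −1.84 and Hlf, a stem cell factor, at −0.08 (adjusted p between 0.481 and 0.965). Mpo, the myeloperoxidase gene, had 0.44, Elane, neutrophil elastase, 1.79, Gata1 1.79, Csf3r 1.22, Ccr2 3.58, Fcgr3 1.30, Fcgr2b −0.29, Ptprc −0.39 and Cxcr4 0.00 (adjusted p of 0.313 or more).

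**Figure D1:**
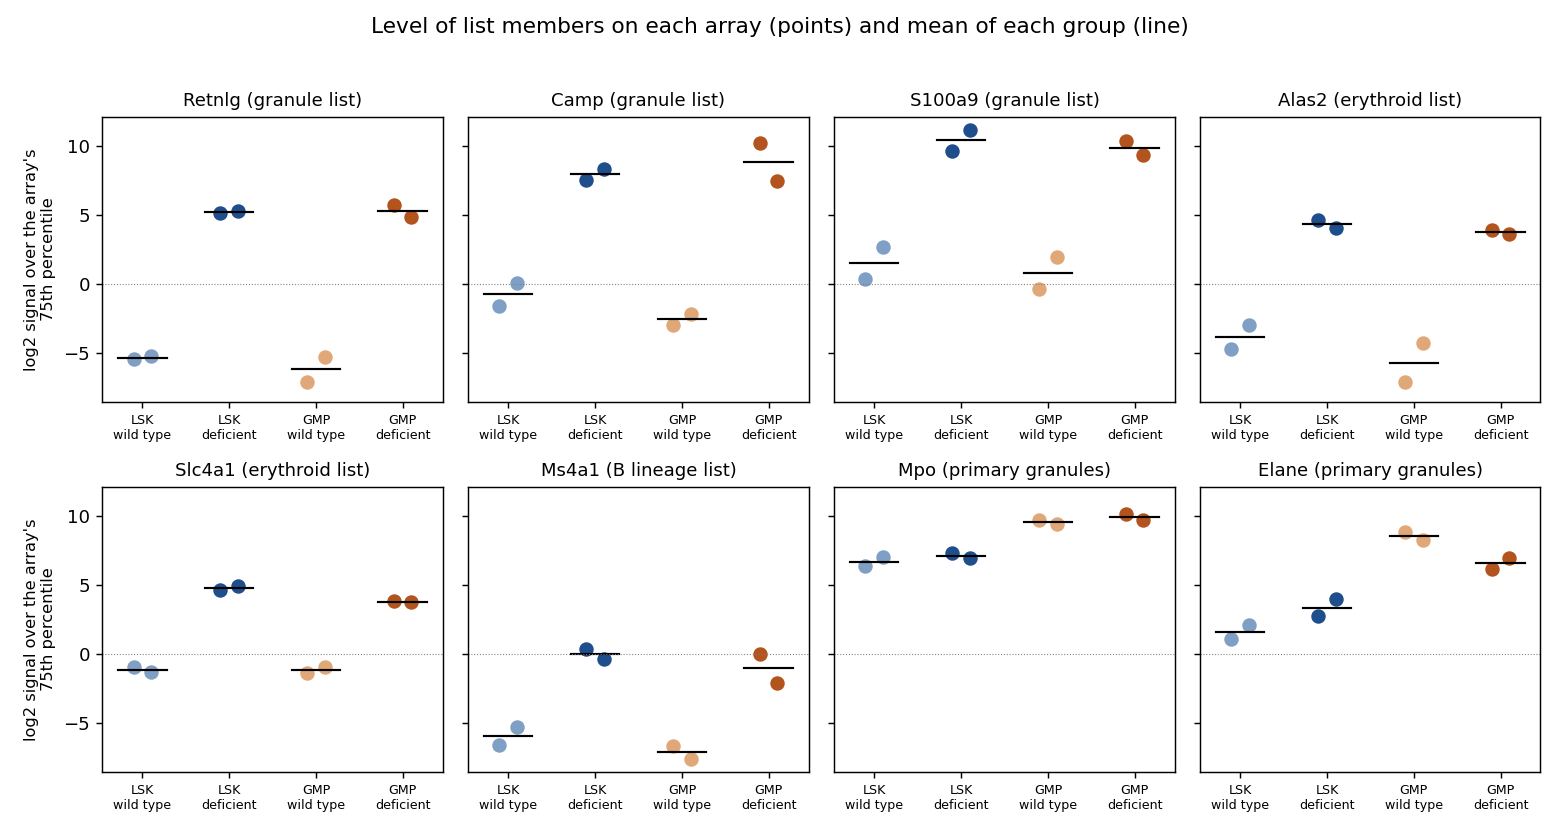
Levels on each array of 8 members of the fixed lists, as log2 signal over the 75th percentile of the array (points, 2 arrays per group) with the group mean (line). Retnlg lies at 5.25 and 5.32 on average in deficient LSK and GMP against −5.36 and −6.20 in wild type, while Mpo differs more between populations than between genotypes.

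The second comparison asked the same of GMP. Members of the granule list were again among the most changed genes. Retnlg rose by a log2 of 11.52 (SE 0.756, limma, adjusted p = 0.00114), at least 1830-fold, from −6.20 (SD 1.29) to 5.32 (SD 0.60), Camp by 11.44 (SE 0.988, adjusted p = 0.00365), Ngp by 10.56, S100a9 by 9.10 and Ltf by 9.07. Red-cell genes rose as well, with Hbb-bt, an adult beta globin gene, higher by 9.72 (SE 0.782, adjusted p = 0.00365), Alas2 by 9.50 and Rhd by 8.92. Ifi202b, an interferon-inducible gene, rose by 9.03 (adjusted p = 0.0134) and Sirpb1b at least 187-fold. Of the named called genes of GMP, Ngp, Alas2, Ifi202b, Rhd and Hbb-b2 were well above background on 1 of the 2 wild-type arrays. Globin genes have near-identical copies, which their probes may not tell apart.

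There were 41 features higher and 0 lower in deficient GMP, 35 of them with a symbol, and 1356 features at an unadjusted p under 0.05 by limma. The last number does not exceed a share of 0.05 of the 28088 features, which would pass with no difference. On the lower side Hgfac had −3.20, Dusp23 −2.76, Fam20c −3.84, Leng8 −2.48 and Ppox, an enzyme of haem synthesis, −2.58, and none passed (adjusted p between 0.431 and 0.674). The count was 2 without deficient GMP replicate 1, 12 and 20 without wild-type GMP replicate 2 and 1, 22 without either deficient LSK array, 27 without either wild-type LSK array, 2 under quantile normalization and 0 in a fit of the GMP arrays alone (1540 at an unadjusted p under 0.05). With both arrays that stood apart left out, 1 feature passed, and of the 17 named called genes of GMP, 2 passed without deficient GMP replicate 1.

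The granule list rose in deficient GMP by a median of 5.67 (camera, adjusted p = 1.57e-30, and adjusted p = 0.0143 with an estimated correlation), with 8 of 20 members called and 16 adjusted over the list alone. S100a8 had 6.21 and Lcn2 2.64, which did not pass (adjusted p = 0.0509 and 0.582). The erythroid list rose by 3.07 (adjusted p = 1.73e-27, and adjusted p = 0.0254 with an estimated correlation), with 6 of 27 called, among them Hbb-b2 by 8.85 and Aqp1, a red-cell water channel, by 6.68, and 17 adjusted over the list alone. Hba-a2 had 7.97 and did not pass (adjusted p = 0.098). The B lineage list rose by 2.47 (adjusted p = 2.86e-09, and adjusted p = 0.0254 with an estimated correlation), or 2.16 with members at their bound. Ms4a1 rose at least 29.2-fold and Fcrla at least 8.66-fold, and 9 of 15 members passed adjusted over the list alone, while Cd79b had −0.91. Without both arrays that stood apart the 3 medians were 5.31, 3.37 and 1.96, and all 3 were called.

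Megakaryocyte and platelet genes had a median of 1.61 in GMP (adjusted p = 1.06e-06), stem cell identity 0.72 (adjusted p = 0.000321), lymphoid priming 0.72 (adjusted p = 0.000297), T and NK genes 0.83 (adjusted p = 0.00507), the interferon response 0.82 (adjusted p = 0.00112) and chemokine receptors 0.32 (adjusted p = 0.046). None of the 6 had a member called over all features, and 7, 3, 4, 0, 1 and 1 members passed adjusted over the list alone, with limma. Lower lists were the granulocyte-monocyte programme with −0.73 (adjusted p = 0.0242), glycolysis with −0.65 (adjusted p = 0.0121) and immediate early genes with −0.35 (adjusted p = 0.046), with 0 members called or adjusted over the list alone. These 9 were not called with an estimated correlation, with adjusted p from 0.351 to 0.547. Without deficient GMP replicate 1, which stood apart, the 3 lower lists and chemokine receptors lost the call (medians −0.43, −0.37, −0.045 and 0.000114), and the first 5 higher lists kept it with medians of 0.733, 0.594, 0.563, 0.566 and 0.122. T and NK genes lost it without deficient GMP replicate 2 (1.34, adjusted p = 0.0783), the programme without wild-type GMP replicate 2 (−0.70, adjusted p = 0.0641), and the interferon response, immediate early genes and chemokine receptors without wild-type GMP replicate 1 (0.41, −0.094 and 0.28). Chemokine receptors also lost it without either wild-type LSK array (adjusted p = 0.0544).

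Neutrophil surface receptors had a median of −0.034 and a mean of 0.70 in GMP (adjusted p = 0.251), although Fpr2 rose at least 122-fold and C5ar1 at least 20.7-fold. With the replicate number as a block that list was called (camera, adjusted p = 0.0418, with a test pointing up). Its median was −0.177 without deficient GMP replicate 1. Primary granules had −0.21 (adjusted p = 0.0502), mitosis −0.16, DNA replication −0.025, respiratory chain genes 0.30, haem biosynthesis 0.25, and dendritic cell and MHC class II genes 0.95 (adjusted p = 0.0567). Mitosis was called lower in 4 of 21 settings, such as normexp correction (−0.229, camera, adjusted p = 0.0213) and the mean of a gene's probes (−0.474, adjusted p = 0.0488). Primary granules were called lower in 9 of 21 settings, such as normexp correction (−0.382, adjusted p = 0.000367) and the GMP arrays alone (adjusted p = 0.0338), and dendritic cell genes higher in 7 of 21, though with a median of 0.313 without deficient GMP replicate 1. Ribosomal proteins had 0.45, heat shock genes 0.24, and monocyte and macrophage genes 0.070, each with a test pointing down (adjusted p = 0.985, 0.458 and 0.985). The chromosome 1 neighbours had 0.26 (adjusted p = 0.166), with 3 of 74 called and 6 higher and 1 lower adjusted over the list alone, among them Itln1 at least 130-fold. Elane had −2.00, Mpo 0.37, Fcgr3 −2.06, Fcgr2b −1.27, Cxcr2 1.94, Ccr2 1.24, Gata1 2.16, Flt3 1.59, Ly6a −1.93, Kit −0.62, Cd34 0.64, Hlf 0.28, Csf3r 0.16, Cxcr4 0.32 and Ptprc −0.37, and none passed (adjusted p between 0.648 and 1).

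**Figure D2:**
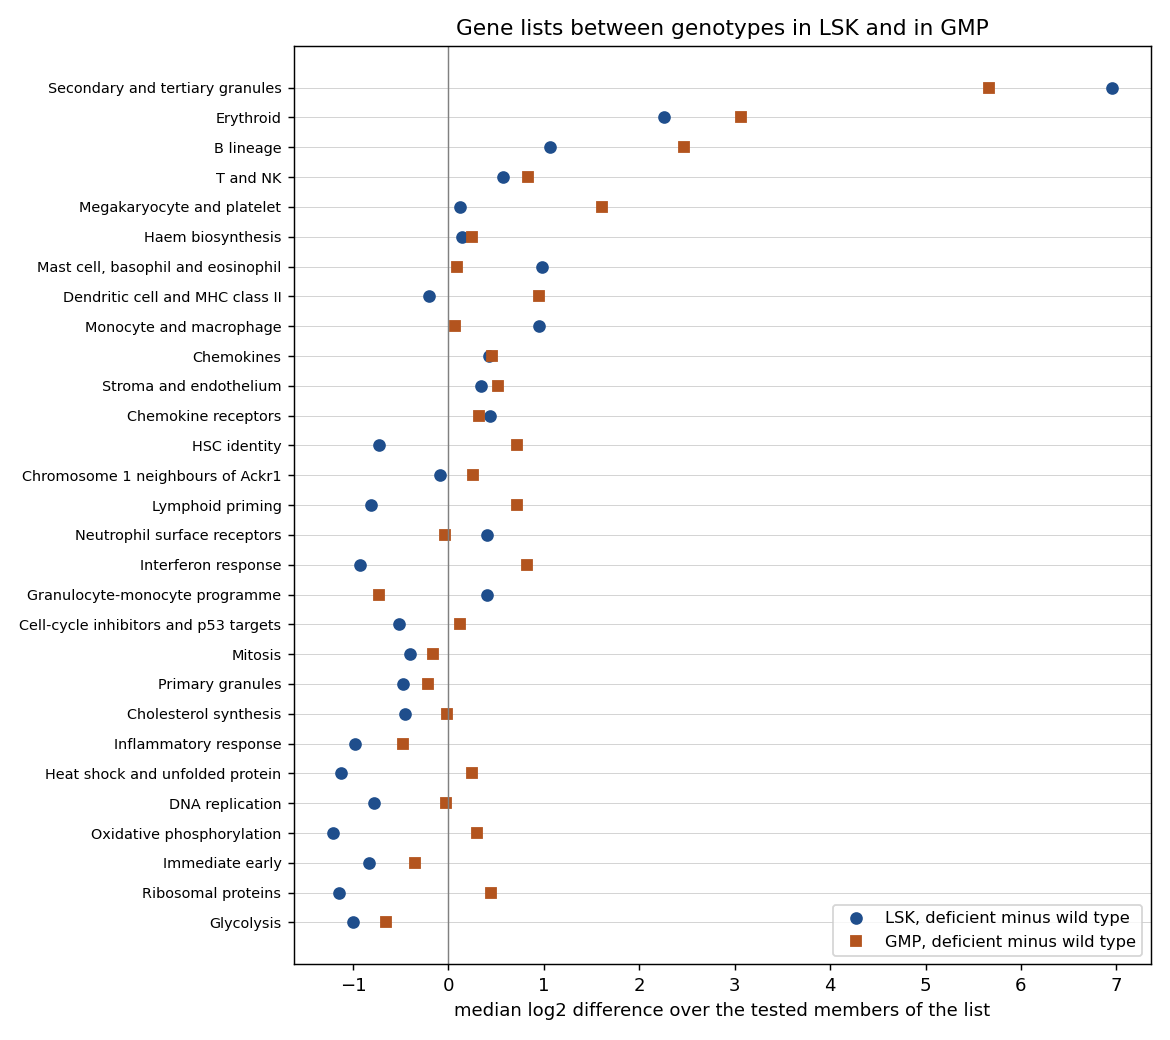
Median log2 difference between genotypes over the tested members of each list, in LSK (circles) and GMP (squares), lists ordered by the averaged difference. The granule list lies at 6.95 and 5.67, the erythroid list at 2.26 and 3.07 and the B lineage list at 1.06 and 2.47, while ribosomal proteins lie at −1.15 in LSK and 0.45 in GMP.

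The third question was whether the genotypes differed alike in both populations. Of the 67 features called in LSK and the 41 called in GMP, 28 were shared. The comparisons share no array, but 1 fit gave both a common spread for each feature, which favours features of low spread in both, so a count for independent lists is no null value here. At an unadjusted p under 0.01 in both, 145 of 521 and 376 higher features were shared, and on the lower side 1 of 55 and 22. With each population fitted on its own arrays, an alternative chosen after seeing the data, 124 of 455 and 346 higher features were shared at that threshold, against 5.60 for independent lists, and 1 of 28 and 25 lower ones, while GMP alone called 0 features. Across all features the differences correlated with r = 0.427 and rho = 0.326, and 60.8% had the same sign. Genes are not independent replicates, so these describe the arrays.

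Averaged over both populations, deficient arrays had higher Retnlg (11.06, SE 0.534, limma, adjusted p = 6.27e-05, at least 1690-fold), Ngp (10.26), Camp (10.08), S100a9 (9.01) and Itgb2l (at least 257-fold), with adjusted p between 0.000386 and 0.000648 for the latter 4. There were 165 features higher and 2 lower. The named lower gene was Dusp23, which fell by 2.85 (SE 0.513, adjusted p = 0.0466), from 0.27 and 0.94 on the wild-type LSK arrays to −1.64 and −3.05, and from 1.78 and 1.00 to −1.57 and −1.17 in GMP. It kept this call in 5 of 19 settings and lost it without 7 of the 8 arrays in turn. Rap1gap had −2.05, Nfkbid −1.93, Ifitm2 −3.29 and Ppp1r35 −2.32, which did not pass (adjusted p between 0.201 and 0.263). Erythroid Hba-a2 (8.30, adjusted p = 0.00624) and Hba-a1 (7.75, adjusted p = 0.0182) were called here. So were B lineage Ms4a1 (at least 42.8-fold), Spib (4.23) and Vpreb3 of the pre-B cell receptor (4.19), with adjusted p between 0.00247 and 0.0114. The count was 86 and 70 without wild-type LSK replicate 1 and 2, 92 without deficient LSK replicate 2, 92 without wild-type GMP replicate 2, 74 without deficient GMP replicate 1 and 103 with both arrays that stood apart left out, 94 of them shared. Quantile normalization gave 46, and the all-feature median moved from 0.166 to −0.093.

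Of the lists, 16 of 20 granule members were called in the average and 16 adjusted over the list alone (median 5.66, camera, adjusted p = 3.62e-32, and adjusted p = 0.0129 with an estimated correlation). The erythroid list had 12 of 27 called and 19 adjusted over the list alone (2.31), and the B lineage list 5 of 15 and 8 (1.96), each with adjusted p = 0.0349 with an estimated correlation. Neutrophil receptors had 5 of 27 called and 8 adjusted over the list alone, including C5ar1 (at least 27.0-fold), Cd177 (at least 24.3-fold) and Fpr1 (4.04), but a median of 0.044 (adjusted p = 0.0149, and adjusted p = 0.394 with an estimated correlation). That call was lost under normexp correction (−0.136, adjusted p = 0.397), without wild-type LSK replicate 1 (−0.114, adjusted p = 0.112), without deficient LSK replicate 1 (adjusted p = 0.526) and without deficient GMP replicate 2 (adjusted p = 0.106). Single called members of other lists were Fn1, fibronectin (4.43), Fcer1a, the high-affinity IgE receptor chain (4.49), Rsad2, an antiviral gene (3.27), Ccl6, a chemokine (3.04), and Cxcr2 (3.20), and each of the 5 lost the call without at least 5 of the 8 arrays in turn. The Fcer1a value is not exact, as 0 wild-type and 1 deficient LSK array were well above background at its probe. Among the chromosome 1 neighbours 5 were higher and 1 lower of 74, with 7 higher and 2 lower adjusted over the list alone (median 0.092, adjusted p = 0.354), and Ifi202b (6.52) and Itln1 (at least 82.5-fold) were among the higher ones. Ribosomal proteins were lower by a median of −0.51 (adjusted p = 7.25e-05, and adjusted p = 0.366 with an estimated correlation) and respiratory chain genes by −0.43 (adjusted p = 7.92e-05, and 0.435 as adjusted p with an estimated correlation). Both averages come mainly from LSK, as the medians in GMP were 0.45 and 0.30, or 0.039 and −0.145 without deficient GMP replicate 1. Respiratory chain genes lost the call under quantile normalization (−0.26, adjusted p = 0.0764). In all, 9 lists were called higher and 7 lower in the average, and between 13 and 18 were called without each array in turn. The split moved to 4 higher and 9 lower under normexp correction, and to 8 and 2 under quantile normalization. Of the lists called in the main fit, the 13 other than granules, erythroid and B lineage were not called with an estimated correlation (adjusted p between 0.366 and 0.697). The programme had a median of −0.053 and a mean of 0.22, and the interferon response a median of 0.028 with a test pointing down, and neither was called.

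The difference between the genotype effects in GMP and in LSK was tested for each gene, and 0 of 28088 features passed with limma (695 at an unadjusted p under 0.05), against 14 with the replicate number, which is also the slide row, as a block. Jchain, the immunoglobulin joining chain, had 8.21, Pdzk1ip1 4.91, Wfdc17 5.40, Ltb, lymphotoxin beta, 4.49 and Wfdc18 5.91. Inpp5j had −5.95, C3, the complement component, −5.60, Mogat2 −6.14, Hp −6.23 and Cebpe −5.10 (adjusted p between 0.638 and 0.961). Jchain and Wfdc18 were not well above background on either wild-type GMP array, nor Inpp5j on either wild-type LSK array, so their values are not exact. So genes called in LSK and not in GMP, such as Hp and Cebpe, were not shown to differ between the populations.

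The populations were then compared within wild type, as GMP minus LSK. Lists of granulocyte, monocyte and mast cell genes were called higher in GMP and those of stem cell, lymphoid and interferon genes higher in LSK. With an estimated correlation only the mast cell list kept its call (camera, adjusted p = 0.0278, and between 0.0618 and 0.218 for the others). Elane rose by a log2 of 7.0 (SE 0.733, limma, adjusted p = 0.00358), from 1.59 (SD 0.69) to 8.59 (SD 0.38). Ms4a3, a gene of granulocyte-monocyte progenitors, rose by 7.68 (SE 0.871, adjusted p = 0.00433), F13a1, coagulation factor XIII, by 7.67, Hp by 7.61 and Igsf6 by 7.04. Nrg1 rose by 8.12, Trem3 by 7.94 and Apba1 by 6.93, each well above background on 1 of the 2 LSK arrays, Tmem178 at least 85.2-fold and Slc36a2 at least 53.8-fold. On the lower side Jchain was at least 1040-fold lower in GMP (log2 difference −10.03, SE 0.887, adjusted p = 0.00358), Gimap8 at least 287-fold, Mn1 at least 285-fold, Wfdc18 at least 229-fold and Ddx4 at least 173-fold. Sgsm1 was at least 145-fold lower, Esam, an endothelial adhesion molecule that stem cells also carry, at least 121-fold, Gucy1a1 at least 115-fold, and Robo4 and the transcription factor gene Mycn, each well above background on 1 of the 2 GMP arrays, had −8.55 and −8.38.

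In total 141 features were higher and 381 lower in wild-type GMP, so 27% of the 522 called were higher. Fcgr3, part of the GMP gate, was higher by 5.94 (adjusted p = 0.0284) and Ccr2, a monocyte chemokine receptor, by 5.46 (adjusted p = 0.0168), whereas Hlf had −4.53 and Flt3 −5.99 (adjusted p = 0.0188 and 0.0168). Mpo had 2.90 (adjusted p = 0.0586), Fcgr2b 4.05, Cxcr2 2.15, Cxcr4 1.28, Cd34, also part of the GMP gate, −1.05, Kit −0.64, Ly6a 0.16 and Csf3r −0.12, which did not pass (adjusted p up to 1). Ly6a encodes Sca1, for which the LSK gate is positive and the GMP gate negative. Its probe did not set the populations apart. The count was 16 and 42 without wild-type LSK replicate 1 and 2 and 87 and 74 without wild-type GMP replicate 1 and 2, and it was 84 with 34.5% higher under quantile normalization, 319 with 38.2% higher under normexp correction and 1337 from the wild-type arrays alone. The fit with both arrays that stood apart left out also gave 1337, of which 518 were among the 522, and of the 63 named called genes 9 passed without wild-type LSK replicate 1.

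The monocyte and macrophage list rose by a median of 3.59 in GMP (camera, adjusted p = 8.67e-19, and adjusted p = 0.0669 with an estimated correlation), with 10 of 20 called and 13 adjusted over the list alone, including Ly86 (5.54). The granulocyte-monocyte programme rose by 2.96 (adjusted p = 1.34e-18, and adjusted p = 0.0639 with an estimated correlation), with 7 of 20 called, including Cebpe (6.08), and 15 higher and 1 lower adjusted over the list alone. Primary granules rose by 2.76 (adjusted p = 8.14e-17, and adjusted p = 0.0669 with an estimated correlation), with Ctsg, cathepsin G (5.77), and Cst7 (3.72) among the 4 of 14 called and 9 adjusted over the list alone. Mast cell, basophil and eosinophil genes rose by 2.60 (adjusted p = 1.57e-14, and adjusted p = 0.0278 with an estimated correlation), the 1 list kept that way. Its 9 called members included Hdc, the histamine-forming enzyme (6.44), Prg2, eosinophil major basic protein (6.37), and Prss34, a basophil protease (6.04), and 13 of 23 passed adjusted over the list alone. Secondary and tertiary granules had 0.80, or 0.59 with members at their bound (adjusted p = 0.00152, and adjusted p = 0.133 with an estimated correlation), with Cybb, a subunit of the phagocyte oxidase (6.28), and Mmp8, at least 11.7-fold, among 4 of 20 called and 6 adjusted over the list alone.

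Genes of stem cell identity fell by a median of 2.13 (adjusted p = 2.86e-19, and adjusted p = 0.0618 with an estimated correlation), with 8 of 24 called lower and 14 adjusted over the list alone. Procr, which encodes EPCR, had −5.56, and Gata3 was at least 72.4-fold lower. Lymphoid priming had −2.09, or −1.85 with members at their bound (adjusted p = 6.09e-11, and adjusted p = 0.125 with an estimated correlation), with 6 of 17 called and 10 adjusted over the list alone. Dntt, the terminal transferase of lymphoid progenitors, had −7.03, and Il7r was at least 13.9-fold and Ccr9 at least 46.4-fold lower. The interferon response had −1.75 (adjusted p = 1.57e-14, and adjusted p = 0.218 with an estimated correlation), with 5 of 30 called and 14 adjusted over the list alone, such as Rtp4 (−5.85), Ifi44 (−5.36) and Oas2 (−4.64). Megakaryocyte and platelet genes had −1.23 and dendritic cell and MHC class II genes −1.43 (adjusted p = 2.11e-06 and 0.00081, and 0.138 and 0.089 as adjusted p with an estimated correlation).

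Lists of growth and metabolism were higher in wild-type GMP: glycolysis by 1.44, mitosis by 1.29, DNA replication by 1.03, respiratory chain genes by 1.00 and haem biosynthesis by 0.93 (adjusted p between 1.61e-08 and 0.00644, and between 0.231 and 0.263 as adjusted p with an estimated correlation). Neutrophil receptors were higher by 1.14 (adjusted p = 5.97e-06, and 0.089 as adjusted p with an estimated correlation). Haem biosynthesis and glycolysis lost the call without wild-type LSK replicate 1 (0.56 and 1.10), and dendritic cell genes without replicate 2 (−1.41). Heat shock genes had 0.65, T and NK genes −0.20 and B lineage genes −0.27, or 0 with members at their bound, and these turned to −0.10, 0.012 and 0.057 under quantile normalization. Those 3 lists were called, as were 2 more: stroma and endothelium had −0.42 and immediate early genes −0.39 (over the 5, adjusted p between 0.0137 and 0.0483, and between 0.138 and 0.438 as adjusted p with an estimated correlation). All 5 lost the call without at least 1 array: heat shock genes without replicate 1 of wild-type LSK or GMP (0.63 and 0.45), stroma without wild-type LSK replicate 2 or GMP replicate 1 (−0.18 and −0.23), B lineage and immediate early genes without wild-type LSK replicate 2 (−0.46 and −0.14), and T and NK genes without any of 6 arrays, all but the deficient GMP arrays (turned to 0.051 without wild-type LSK replicate 1).

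Within deficient mice the same contrast of GMP minus LSK gave 0 features with limma, while 4699 had an unadjusted p under 0.05. With the replicate number, which is also the slide row, as a block it gave 688. The 5 named genes with the smallest p on each side all had an adjusted p of 0.0952. Ctsg had 5.66, Ms4a3 5.92, Ly86 5.59, Mt1, a metallothionein, 4.62 and Tctex1d1 6.17. On the lower side Nkx2-3 had −5.36, Sema3d was at least 32.2-fold lower, Hoxa10, a stem cell homeobox gene, at least 22.8-fold, Aebp1 at least 19.3-fold and Wfdc2 at least 18.7-fold. Primary granules had a median of 2.94 (camera, adjusted p = 6.64e-09, and adjusted p = 0.225 with an estimated correlation), with 11 members adjusted over the list alone, respiratory chain genes 2.44 (adjusted p = 4.33e-20, and adjusted p = 0.225 with an estimated correlation) and stem cell identity −1.03 (adjusted p = 0.000258, and adjusted p = 0.291 with an estimated correlation). The last lost the call without deficient LSK replicate 1 (−0.61, adjusted p = 0.19) and had −1.54 without deficient LSK replicate 2. Without deficient LSK replicate 1, which leaves the weak array alone in its group, 4245 features passed, and 129 passed in a fit of the deficient arrays alone.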

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

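The list tests in this part were fixed before the data were examined, while the comparison of spike-in spots and the fits without both arrays that stood apart (deficient LSK replicate 2 and deficient GMP replicate 1) were chosen only after the results were seen. No group held 4 or more arrays, so no array was tested as standing apart from its group.

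For 14 of 29 gene lists the genotype difference in GMP differed from that in LSK by camera with its preset correlation, and 0 of these 14 were called with an estimated correlation, where their adjusted p lay between 0.252 and 0.509. The difference of differences was 1.60 for the interferon response with 30 of 30 members above 0, 1.54 for the respiratory chain with 33 of 33 above 0 and 1.35 for ribosomal proteins with 33 of 34 above 0. It was 1.77 for megakaryocyte and platelet genes, 1.51 for lymphoid priming, 1.39 for stem cell identity and −0.92 for mast cells, basophils and eosinophils. These 7 kept the call without each array in turn, though ribosomal proteins lost it under quantile normalization (0.63, adjusted p = 0.0661). Without both arrays that stood apart, the differences shrank to 0.224 for megakaryocyte and platelet genes, 0.702 for the interferon response and 0.795 for the respiratory chain. Lymphoid priming had 0.896, ribosomal proteins 0.953, stem cell identity 1.25 and mast cells −0.428. Over the arrays left out in turn, megakaryocyte genes ranged from 0.875 to 2.48, the interferon response from 0.979 to 2.45 and mast cells from −1.51 to −0.389.

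The other 7 lost the call when at least 1 array was left out. The granulocyte-monocyte programme had −1.06 (without deficient LSK replicate 1, −1.15 with adjusted p = 0.309). Secondary and tertiary granules had −0.47, neutrophil surface receptors −0.63 and monocytes and macrophages −0.93, each lost without deficient LSK replicate 1 (−0.81, −0.22 and −0.56) or wild-type LSK replicate 1 (−0.66, −0.17 and −0.64). Dendritic cells and MHC class II had 0.84, lost without wild-type LSK replicate 2, deficient LSK replicate 1, wild-type GMP replicate 1 or deficient GMP replicate 2 (0.62, 0.58, 0.57 and 1.14). Cell-cycle inhibitors and p53 targets had 0.94, lost without wild-type LSK replicate 2, deficient LSK replicate 2, wild-type GMP replicate 2 or deficient GMP replicate 1 (1.09, 0.57, 0.56 and 0.70). Heat shock and unfolded protein had 1.24, lost without deficient LSK replicate 2 or deficient GMP replicate 2 (0.59 and 1.59).

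Spike-in spots, 350 per array and outside the main measurement, stood higher over the 75th percentile on the deficient LSK arrays (log2 of 2.67 and 5.78) than on the wild-type ones (0.74 and 1.17), a mean difference of 3.27. In GMP the values overlapped, with 0.22 and 1.95 on deficient and −0.34 and 0.27 on wild-type arrays, a mean difference of 1.12.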

How the results depend on the processing

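The fits with array weights, with both arrays that stood apart left out (deficient LSK replicate 2 and deficient GMP replicate 1) and with crossed replicate numbers, and the overlap with each population fitted alone, were chosen only after the results were seen. Granules, erythroid and B lineage genes kept their call and direction in LSK, GMP and the average in every setting run, except that with an estimated correlation the erythroid and B lineage medians in LSK (2.26 and 1.06) lost the call (adjusted p = 0.101 each). Named called genes kept their direction in every setting in which they were tested, which under the filter on all arrays were 8 of 20 in LSK, 5 of 17 in GMP, 11 of 27 in the average and 32 of 63 in wild type. Of the called lists, 6 of 18 in LSK, 6 of 12 in GMP, 6 of 14 in the difference between them, 4 of 16 in the average, and 13 of 21 and 4 of 12 between populations in wild-type and deficient mice kept the call in every setting apart from the estimated correlation. Quantile normalization ended or turned 8, 4, 4, 6, 4 and 5 of these calls, and normexp correction 5, 2, 2, 5, 1 and 1. The slide and the scan could not be run as a block because there was 1 of each. Where a count moved, the cause was not tested, apart from the fewer arrays or features that a setting itself brings.

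In LSK the 67 features called became 27 with normexp correction, 27 with quantile normalization, 35 with scaling to the median, 6 with no filter, 20 with a filter on all arrays, 37 without both arrays, 1 with array weights and 0 to 2818 without each array in turn. In GMP the 41 became 2 with quantile normalization, 11 with the median, 9 with no filter, 12 with a filter on all arrays, 0 from the GMP arrays alone (1540 at an unadjusted p under 0.05), 1 without both arrays, 75 with array weights and 2 to 36 without each array. In the average the 167 became 88 with normexp, 46 with quantile, 87 with the median, 83 with no filter, 45 with a filter on all arrays, 103 without both arrays, 102 with weights and 70 to 209 without each array. For GMP against LSK in wild type the 522 became 319 with normexp, 84 with quantile, 213 with no filter, 160 with a filter on all arrays, 1337 from the wild-type arrays alone, 1337 without both arrays, 2216 with weights and 16 to 649 without each array. In deficient mice the 0 became 839 with normexp, 129 from the deficient arrays alone and 0 to 4245 without each array. The overlap of 28 became 145 at an unadjusted p under 0.01, and 124 at that threshold with each population fitted alone. Weights must be equal within each group when it holds 2 arrays, so they cannot single out an array. They were 1.41 in wild-type and 0.317 in deficient LSK, and 3.98 in wild-type and 0.561 in deficient GMP.

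The labels give no shared animal or batch for the replicate numbers, but arrays of a population with the same number lay in 1 slide row, so a block on the number is a block on the row. Same-numbered arrays deviated with r = −0.344 in LSK and 0.262 in GMP. With the number as a replicate block 481 features were called in LSK, 195 in GMP, 14 in the difference between them, 905 in the average (75.9% higher against 98.8%) and 688 between populations in deficient mice, and the 20 named called genes of LSK and 17 of GMP kept the call. With the numbers crossed in LSK the counts were 616, 203, 2, 1302 and 1854, and 1077 in wild type.

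Mitosis in LSK turned to 0.43 without deficient LSK replicate 2 and without both arrays, with −1.47 to 0.43 over the arrays left out in turn. DNA replication in LSK had −0.48 with its test turned under quantile normalization, and 0.15 without that array and without both (−1.78 to 0.15 over the arrays). In the difference between GMP and LSK, mitosis turned to −0.61 without that array (−0.61 to 1.25 over the arrays) and −0.36 without both, DNA replication to −0.29, and cell-cycle inhibitors and p53 targets had 0.0027 with the test turned. In the average, mitosis had −0.044 with the test turned without that array (−0.67 to −0.044 over the arrays) and 0.17 without both. The all-feature median in LSK was 0.115, and −0.248, 0.415 and −0.14 under quantile, normexp and median scaling. The weak signal of deficient LSK replicate 2, with 34.3% of spots well above background, limits what LSK can show for dim genes. Its lowest value well above background was −1.44, against −6.69 to −4.81 on the others. The all-feature median in LSK was 0.555 with no filter, 0.382 without deficient LSK replicate 1 and −0.081 without replicate 2. Dim features thus lay higher on the weak array, and how far this adds to the higher calls in LSK was not tested.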

Other observations

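All tests of explanations in this part were chosen only after the results were seen, as was the fit without both arrays that stood apart (deficient LSK replicate 2 and deficient GMP replicate 1). In wild-type mice, further single genes differed between GMP and LSK, while the lists of chemokine receptors and of chemokines were not called (camera, adjusted p = 0.593 and 0.266). Cx3cr1, the fractalkine receptor, was higher by a log2 of 4.09 in GMP, while its ligand Cx3cl1 had −3.74 (limma, adjusted p = 0.0237). Mt1, a metallothionein, and Cd14, a monocyte surface protein, were higher by 5.33 and 5.43, whereas Nr4a1, an immediate early nuclear receptor, had −4.87 and Cdkn1c, a cell-cycle inhibitor of quiescent stem cells, −4.41. Of the 63 named called genes of that comparison, 9 and 21 passed without wild-type LSK replicate 1 and 2, and 24 and 26 without wild-type GMP replicate 1 and 2.

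Transcripts of mature granulocytes, red cells and B cells were higher in deficient samples of both populations, although in LSK the erythroid and B lineage lists lost their call with an estimated correlation (camera, adjusted p = 0.101 each). The genotype, the biological difference the design names, stays open as an untested explanation. Slide column stays open too and cannot be told apart from genotype, as deficient arrays lay in column 1 and wild-type arrays in column 2. A rise of the granulocyte programme within the progenitors would not cover the erythroid and B lineage lists, whose smaller median in the average was 1.96 (camera, adjusted p = 0.0349 with an estimated correlation). Their rise is part of the pattern itself and was known beforehand, so it is no test of that explanation as the whole cause. The 2 arrays that stood apart, as the whole cause, are argued against by the smallest median without them, 0.881. Marrow cells, or their RNA, that the lineage-negative gate should have removed stay open: across the 62 members of the 3 lists the excess in LSK and in GMP on a linear scale correlated with rho = 0.808, but this decides nothing, since 49 of them were higher in both populations and a like change within both may give the same. On the deficient LSK arrays, Hba-a2 reached log2 levels of 10.01 and 12.93 and S100a9 of 9.67 and 11.20, which are probe signals and do not rank genes by abundance. The differences of Cd79a (0.18 in LSK and 0.10 in GMP), Cd79b (−0.82 and −0.91) and Lyz2 (1.83 and 0.10) were not called. Of the 20, 27 and 15 members, 11, 19 and 8 were well above background on every wild-type array, and 1, 3 and 3 are held by another list.

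Of the chromosome 1 neighbours of Ackr1 that no other list holds, 3 of 66 were called in the average (Dusp23, Itln1 and Ifi202b, 4.55%) against 122 of 27457 features that no list holds (0.444%), an odds ratio of 10.7 with a 95% interval from 2.11 to 33.4 (Fisher's exact test, two-sided, p = 0.0034). This test counts the genes that prompted it, so it does not decide for a segment of another strain kept around the disrupted gene through backcrossing, which stays open: at an unadjusted p under 0.05 the numbers were 6 of 66 and 3271 of 27457 (Fisher's exact test, two-sided, p = 0.572). Material of mature cells, the other explanation weighed, stays open for these genes: Itln1 and Ifi202b were higher and 1 was called lower, Dusp23, but that call held in 5 of 19 settings and was lost without 7 of the 8 arrays in turn, so it carries little weight here or in the count of 3. Ifi202b had log2 levels of −4.34 and −5.24 in wild-type LSK, 0.17 and −1.72 in deficient LSK, −5.50 and −5.00 in wild-type GMP, and 5.17 and 2.39 in deficient GMP. A change with the genotype itself was not tested apart from these.

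The female and male genes stood against the label, which calls the mice female. Eif2s3y, a Y-linked gene, was well above background on 8 arrays with signals from 58.1 to 7260, Ddx3y on 7, Uty on 7 and 6 at its probes and Kdm5d on 5, whereas Xist, the X-inactivation transcript, was so on 0 arrays at 1 probe and on 1 array at the other, with signals of at most 17.8 and 23.6. Male mice in every group are a candidate explanation, since 7 of 8 arrays had Eif2s3y and neither Xist probe well above background. The exception was deficient GMP replicate 1, which stood apart and had an Xist signal of 23.6 beside the highest Eif2s3y signal, 7260. RNA of the X-linked copies on the Y-linked probes in female mice stays open, because an Xist probe was well above background on 1 array and neither exceeded the 75th percentile on any, so that these probes were not shown to respond. Whether sex differs between the samples was not tested.

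In the averaged genotype comparison the real split called 167 features and the highest of the other splits called 0, so 1 of 18 splits gave as many, and these splits are too few for a share under 0.05. Most of the other splits put wild-type and deficient arrays in the same group, which adds the genotype difference to their spread. Low counts there were thus favoured beforehand, so the comparison decides nothing about chance.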
